A study of Mus musculus with 16 samples.

How the data were processed

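RNA sequencing was done on 16 libraries of mouse fat, 4 from each of 4 depots: epididymal white fat (eWAT), inguinal white fat (iWAT), thigh adipose tissue (tAT) and brown adipose tissue (BAT). Per the series design, the animals were male C57BL66/J mice made obese by a high-fat diet. Per the labels' protocols, frozen tissue was extracted with Trizol and libraries were built with the TruSeq RNA Sample Prep Kit from 1 µg of total RNA. Depot and replicate number were taken from the sample titles. The labels do not say whether libraries of a depot came from separate mice, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries held identical values, and all 16 were used.

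The deposited values are FPKM (fragments scaled to gene length and to the mapped total of the library), as the authors computed them, for 46386 entries with 46206 distinct symbols. Per the submitters' processing notes, the tools were TopHat, TopHat2 2.0.9 and Cufflinks 2.1.1 and the genome build was mm10; their settings and the annotation are not given in the sources used here. FPKM is a share of a library, so a few abundant genes lower the values of all others. The 10 most abundant genes took 27.6 to 32.1% of the FPKM of BAT libraries and 25.8 to 29.7% of tAT libraries. They took 19.0 to 22.0% of iWAT and 18.1 to 21.0% of eWAT libraries. The BAT shares were computed with 8 mitochondrially encoded genes listed at 0. No counts were used, so the sequencing depth is unknown, and no counting interval or detection floor was computed. Exact zeros occurred in 228 values of 86 genes whose median over the libraries was at least 10 FPKM, for example Gapdh in tAT 1, so a zero can be a failed estimate and such genes are reported only as listed at 0. Whether reads were assigned by strand is not given in the sources used here. Genes with a near-identical copy (Fabp3 and Fabp3-ps1, Atp5g1, the haemoglobin genes) are uncertain, since their reads could be split between copies.

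Differences were computed on log2(FPKM + 1), which understates the change of low genes. The 14991 genes with at least 1 FPKM in at least 4 libraries were tested with limma 3.58.1 (R 4.3.3; lmFit, eBayes with trend and robust) in a single fit of the 16 libraries with a mean per depot, and 6 contrasts were taken: tAT against each other depot, and the other depots against each other. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The calls of a list were also adjusted over its own members. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a contrast, and with fry. List scores per library were compared by exact two-sided permutation tests. Gene spans are from GENCODE vM21, which is on the same build. Figures were drawn with python 3.11.15. The test step was tried on simulated data: in a simulated tAT against iWAT comparison of 14991 genes, 87% of 100 genes changed by 1 and 87% of 100 genes changed by 2 on the log2 scale were recovered, and 11 of 185 calls (5.95%) were false.

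The groups, tests, gene lists, rule for named genes and most other settings were fixed before the data were examined. The 32 lists hold 442 distinct genes: thermogenic genes that muscle hardly expresses, thermogenic genes shared with muscle, brown-selective, beige-selective, white-selective and general adipocyte genes, respiratory complex I, complexes II to IV, ATP synthase, citric acid cycle, fatty acid oxidation, lipogenesis, glycolysis, branched-chain amino acid breakdown, creatine and calcium cycling, adipokines, skeletal muscle, macrophage, inflammation, lymphocytes and lymph node, endothelium, Schwann cells, mesothelium, skin, epididymis, preadipocytes, extracellular matrix, posterior Hox, anterior Hox, limb and position, blood, and stress response. Some genes stand in more than 1 list. Acta1, Cox4i1, Fbxo31, Hbb-b1 and Hbb-b2 had no match by symbol or synonym and were not analysed here, and Gyk was matched as Gk.

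The rule for named genes took, in each tAT contrast, the 8 largest rises and 8 largest falls among genes that passed, whose libraries did not overlap between the depots, with a mean of at least 5 FPKM in the higher depot and a symbol that is not a Gm, Rik or LOC name (3 each way in the other contrasts). It always took Ucp1, Cidea, Dio2, Ppargc1a, Prdm16, Elovl3, Cox8b, Adrb3, Zic1, Lhx8, Tnfrsf9, Tmem26, Tbx1, Lep, Slc7a10 and Adipoq. In each list it took up to 2 passing members with the largest rise and up to 2 with the largest fall, or else the 2 with the highest level. Some genes it took are not reported here and were left out of the counts of named differences, though not of the lists. Of the others, the text names those that carry a comparison.

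Other settings chosen in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, fits of 2 depots alone, the replicate number as a block, array quality weights, the muscle score as a covariate, a threshold of 1 on the log2 difference, an estimated correlation in camera, and leaving out each library in turn. Chosen after seeing the data were exact zeros of abundant genes set to missing, the libraries rich in muscle genes (tAT 1, 2 and 4, BAT 3 and 4) left out, and eWAT 3 left out, which leaving out each library also covers. Leaving out the muscle-rich libraries left tAT with 1 library, which limma then assumes to vary like the other groups. A setting was said to change a result when it moved it across the threshold or turned its sign, and a turned sign where neither value passed was not counted.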

Results

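The series title asks for a fat depot of the mouse that is beige by nature, and the samples set fat from the thigh (tAT) beside 3 depots of known kind. Brown adipose tissue (BAT) burns fuel for heat, inguinal fat (iWAT) is a subcutaneous white depot, and epididymal fat (eWAT) is a visceral white depot next to the epididymis. Beige adipocytes are heat-producing cells that lie within white fat. RNA was sequenced from 4 libraries of each depot, 16 in all, from obese male C57BL66/J mice on a high-fat diet. The deposited values were FPKM, so the number of reads behind them is unknown. Their sum per library ranged from 818815 in BAT 4 to 1074120 in tAT 3, and 12447 to 14286 genes per library reached 1 FPKM. Levels below are means ± SD of the 4 libraries of a depot, differences are on the log2(FPKM + 1) scale, and adjusted p-values are from limma unless another test is named. Across genes, which are not independent replicates, the median Spearman correlation between libraries was 0.947 within tAT, 0.917 between tAT and iWAT, 0.873 between tAT and BAT, and 0.868 between tAT and eWAT.

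Ucp1 (ENSMUSG00000031710.3, mm10 chromosome 8, 83290352 to 83298452) encodes the uncoupling protein through which brown adipocytes make heat. It stood at 4536 ± 637 FPKM in BAT, 270.3 ± 165 in tAT, 0.243 ± 0.0477 in iWAT and 0.0819 ± 0.0508 in eWAT (n = 4 each), and the 4 thigh libraries held 114, 152, 461 and 354 FPKM. Cidea (chromosome 18, 67343604 to 67367785), a lipid droplet protein of brown adipocytes, and Cox8b (chromosome 7, 140898945 to 140900446), a cytochrome oxidase subunit of brown fat and muscle, followed the same order of depots. Cidea stood at 1797 ± 183, 181 ± 120.3, 14.7 ± 3.73 and 2.75 ± 0.466 FPKM, and Cox8b at 5892 ± 823, 1052 ± 529, 121 ± 37.4 and 44.9 ± 14.5 FPKM. The score of 12 thermogenic genes that muscle hardly expresses, their mean log2(FPKM + 1), was 6.70 ± 0.215 in BAT, 4.20 ± 0.394 in tAT, 2.27 ± 0.105 in iWAT and 1.97 ± 0.0468 in eWAT. In an exact two-sided permutation test of 4 against 4 libraries, each of these depots differed from tAT with p = 0.0286, the smallest p this design allows, and adjusted over all scores the p was 0.0538 against iWAT and 0.0416 against BAT and against eWAT.

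**Figure D1:**
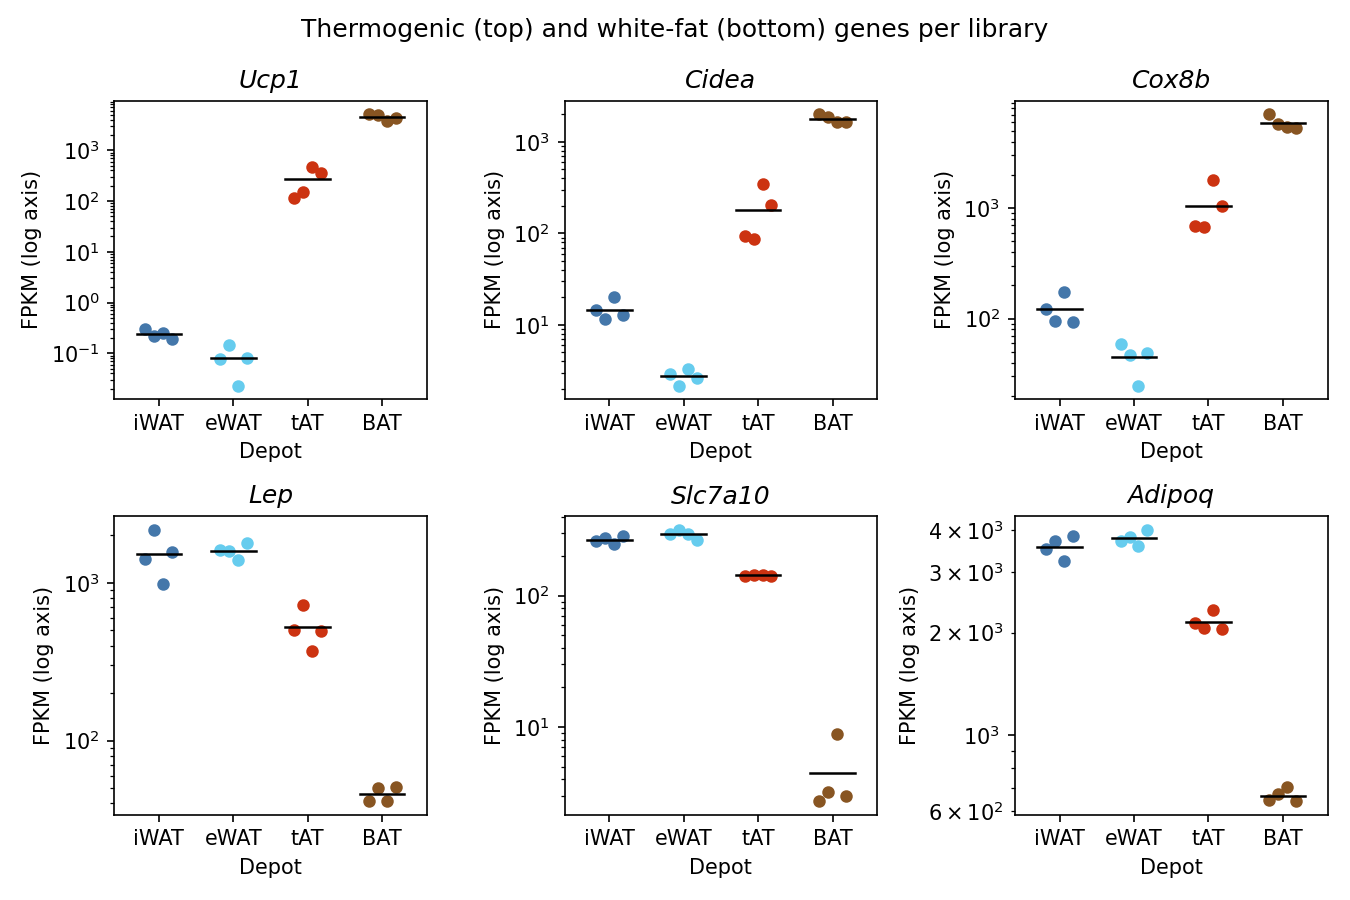
FPKM (log axis) of Ucp1, Cidea, Cox8b, Lep, Slc7a10 and Adipoq in each library, by depot; points are libraries and bars are the means of 4. The 4 thigh libraries lay between inguinal and brown fat for each of the 6 genes, for instance at 114 to 461 FPKM for Ucp1.

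Transcripts of skeletal muscle were abundant in some libraries of fat. The measured genes of the muscle list summed to 31336, 31426 and 19893 FPKM in tAT 1, 2 and 4, against 339 in tAT 3. They summed to 3831 and 3134 FPKM in BAT 3 and 4, to 157 and 136 in BAT 1 and 2, to 140 to 869 in iWAT, and to no more than 98.8 in eWAT. tAT 1, 2 and 4 and BAT 3 and 4 are called the muscle-rich libraries from here on. The thermogenic score was 3.90, 3.83 and 4.54 in tAT 1, 2 and 4 and 4.55 in tAT 3, the thigh library with the fewest muscle transcripts.

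**Figure D2:**
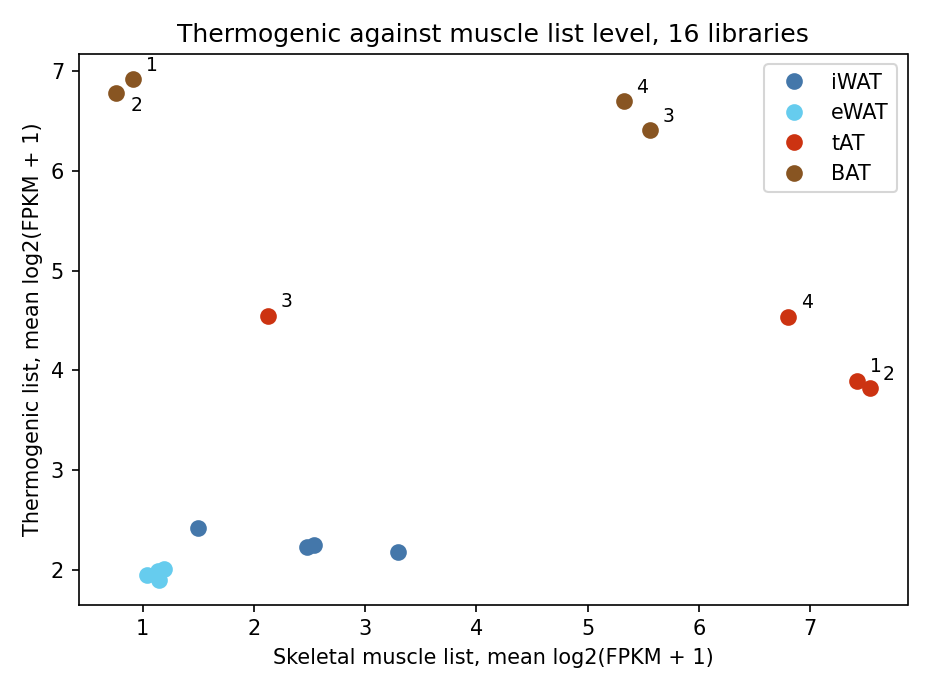
Mean log2(FPKM + 1) of the thermogenic genes that muscle hardly expresses (y axis) against that of the skeletal muscle genes (x axis) in the 16 libraries; each point is a library, and thigh and brown libraries carry their number. tAT 3 had a muscle score of 2.13, against 6.80 to 7.54 in the other thigh libraries, and its thermogenic score of 4.55 was the highest of the depot.

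Thigh fat was set against inguinal fat to compare it with the white depot under the skin. In each of the thermogenic lists 10 of 12 genes rose in thigh fat, and these list calls held with an estimated correlation. Of the measured genes, 7 of 10 white-selective, 15 of 18 macrophage and 14 of 16 matrix genes fell, but these list calls were lost (adjusted p = 0.321, adjusted p = 0.448 and adjusted p = 0.448 with an estimated correlation). Ucp1 was higher by 7.54 (SE 0.32, adjusted p = 7.8e-09), Cidea by 3.33 (adjusted p = 1.16e-05) and Cox8b by 3.03 (adjusted p = 1.03e-05). Leptin, the satiety hormone of white fat, was lower: Lep (chromosome 6, 29060220 to 29073877) stood at 523 ± 149 FPKM against 1535 ± 496 (log2 difference -1.54, adjusted p = 8.51e-05). Slc7a10, an amino acid transporter of white adipocytes, stood at 143 ± 1.42 against 268 ± 17.3 FPKM (-0.90, adjusted p = 0.00442), and Adipoq, the adiponectin gene, at 2143 ± 128 against 3572 ± 254 (-0.74, adjusted p = 2.11e-05).

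Among the thermogenic genes that muscle hardly expresses, 10 of 12 rose in thigh fat and 0 fell (10 and 0 adjusted over the list alone), with a mean difference of 1.93 (camera adjusted p = 7.82e-10, and adjusted p = 0.048 with an estimated correlation). Fry, which tests whether the genes of a list move one way on balance, gave adjusted p = 1.1e-06. Besides Ucp1 and Cidea, Adrb3, the adrenergic receptor that switches on lipolysis and heat production, was higher by 0.89 (adjusted p = 0.0148). Dio2, which makes active thyroid hormone, was higher by 2.21 (adjusted p = 0.0122), a call lost when only these depots were fitted (adjusted p = 0.0568), and Dio2 in iWAT 2 stood at 6.73 FPKM against 0.203 to 0.323 in the other iWAT libraries. Prdm16 (chromosome 4, 154316125 to 154636873), a regulator of brown and beige cell fate, stood at 5.12 ± 0.790 against 3.58 ± 0.681 FPKM, a difference of 0.42 (adjusted p = 0.0421). Its call did not outlast single libraries: the adjusted p was 0.0801 without tAT 1, 0.0526 without tAT 2, 0.13 without tAT 4, 0.103 without iWAT 3, 0.121 without iWAT 4 and 0.0514 without eWAT 2. Elovl3, an elongase of very long fatty acids, stood at 0.785 against 0.304 FPKM (adjusted p = 0.246).

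Of the oxidative genes that thermogenic fat shares with muscle, 10 of 12 rose (12 adjusted over the list alone), with a mean of 2.53 (camera adjusted p = 2.02e-13, and adjusted p = 0.00203 with an estimated correlation). The score of this list was 5.51, 5.48 and 5.74 in the muscle-rich tAT 1, 2 and 4 and 5.03 in tAT 3, against 2.80 to 3.13 in iWAT. Fabp3 (chromosome 4, 130308595 to 130315463), a fatty acid binding protein of heart and brown fat, stood at 98.9 ± 38.6 against 1.06 ± 1.06 FPKM (5.63, adjusted p = 1.23e-07). Its pseudogene Fabp3-ps1 also rose (4.31), but reads may be shared between the copies and its value is uncertain. Cpt1b, which moves fatty acids into mitochondria, stood at 108 ± 24.8 against 5.31 ± 1.03 FPKM (4.10, adjusted p = 3.3e-09), and Cox7a1, a cytochrome oxidase subunit, at 348 ± 114 against 28.7 ± 4.48 (3.51, adjusted p = 1.5e-08). Ppargc1a, a coactivator of mitochondrial biogenesis, was higher by 1.13 (adjusted p = 8.75e-05).

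For markers said to separate classical brown from beige cells, no list test passed against iWAT. Of 7 measured brown-selective genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; 2 and 1 without tAT 4), and the mean of -0.18 and median of -0.00425 were opposite in sign to the upward direction of the test (camera adjusted p = 0.307). The mean was -0.12 without iWAT 3. Lhx8, a homeobox gene, fell by 1.25 (adjusted p = 3.73e-05), while Mpzl2 rose by 1.15 and Oplah by 1.02. Of 6 measured beige-selective genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; mean -0.44, camera adjusted p = 0.572), Ear2 among them (-2.03, adjusted p = 0.000176). Tbx1 (chromosome 16, 18580979 to 18590671), a beige marker, stood at 3.76 ± 2.76 against 1.34 FPKM (0.72, adjusted p = 0.225), and differed by -1.20 without the muscle-rich libraries (adjusted p = 0.00699) and by 1.36 without tAT 3 (adjusted p = 4.83e-05). Tnfrsf9 and Tmem26, a pair of beige markers, averaged 0.138 and 0.0498 FPKM in tAT and were too low to be tested.

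The enzymes of the citric acid cycle rose in thigh fat, 13 of 13 (13 adjusted over the list alone), with a mean of 0.70 (camera adjusted p = 1.26e-10, and adjusted p = 0.321 with an estimated correlation). Sucla2, a subunit of succinyl-CoA synthetase, stood at 233 ± 66.4 against 109.7 ± 11.4 FPKM. For the 37 subunits of respiratory complex I the mean was 0.23, with 9 higher and 0 lower (9 and 0 adjusted over the list alone), for 22 of complexes II to IV it was 0.33, with 9 higher and 0 lower (9 and 0 adjusted over the list alone), and for 15 of ATP synthase 0.21, with 2 higher and 0 lower (2 and 0 adjusted over the list alone). Their camera adjusted p-values were 2.52e-06, 3.51e-06 and 0.00361, and each had adjusted p = 0.448 with an estimated correlation. Without tAT 3 the means were 0.08, 0.15 and 0.10. Complex I then had 8 higher and 4 lower, and ATP synthase lost its call (camera adjusted p = 0.139). Complex I had 15 higher without tAT 2, and ATP synthase 4 without iWAT 3. Ndufs1 of complex I was higher by 0.83 and Uqcrc2 of complex III by 0.72. Of 16 fatty acid oxidation genes 9 rose (10 adjusted over the list alone; mean 0.55, camera adjusted p = 3.2e-07, and adjusted p = 0.448 with an estimated correlation; mean 0.36 without tAT 3), and Acadvl, a dehydrogenase of long-chain fatty acids, stood at 277 ± 116 against 114 ± 9.47 FPKM.

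Of 13 lipogenesis genes, 5 rose (5 adjusted over the list alone; mean 0.66, camera adjusted p = 0.000924, and adjusted p = 0.448 with an estimated correlation), and iWAT 4, where the desaturase gene Scd1 was listed at 0, had a score of 5.84 against 6.67 to 6.83 in the other iWAT libraries. Without iWAT 4 the mean was 0.44 and 3 genes rose, and 3 rose also without tAT 4 or iWAT 2. Among those that rose was Acacb, whose product makes the malonyl-CoA that restrains fatty acid entry into mitochondria (59.5 against 13.9 FPKM). The 13 glycolysis genes had a mean of 0.17 with 5 higher and 1 lower (5 and 1 adjusted over the list alone), and the 15 genes of branched-chain amino acid breakdown a mean of 0.13 with 3 higher and 0 lower (2 and 0 adjusted over the list alone). Their camera adjusted p-values were 0.0079 and 0.0134, and both had adjusted p = 0.448 with an estimated correlation. The glycolysis mean was 0.34 without tAT 1, where Gapdh was listed at 0, 0.0692 without tAT 2 and 0.10 without tAT 4. Without tAT 3 the mean of branched-chain amino acid breakdown was 0.05 and its call was lost (camera adjusted p = 0.229), with 2 higher and 2 lower. Pkm, a pyruvate kinase gene that muscle also expresses, was higher by 1.22. The 7 measured genes of creatine and calcium cycling had a mean of -0.15 but a median of 0.06 (camera adjusted p = 0.845), with 1 higher and 3 lower (1 and 3 adjusted over the list alone). The mean was -0.0839 without iWAT 2, and 2 were higher without tAT 3. Gamt, of creatine synthesis, was among those lower (-1.14, adjusted p = 1.01e-06).

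Of 10 white-selective genes 0 rose and 7 fell (0 and 7 adjusted over the list alone; mean -0.72, camera adjusted p = 0.0316, and adjusted p = 0.321 with an estimated correlation). Of 14 general adipocyte genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; mean -0.19, camera adjusted p = 0.73). Among them Lpl, the lipase that takes up circulating fat, differed by -0.75 and Slc2a4, the insulin-responsive glucose transporter, by 0.55. Of 15 measured adipokines 2 rose and 8 fell (2 and 9 adjusted over the list alone; mean -0.59, camera adjusted p = 0.113). Sfrp5, a secreted Wnt antagonist, stood at 84.0 ± 27.2 against 278 ± 53.8 FPKM, and Nrg4, a growth factor secreted by brown fat, at 110.3 ± 19.5 against 67.0 ± 10.3.

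Of 18 macrophage genes 15 fell (17 adjusted over the list alone; mean -1.21, camera adjusted p = 3.44e-05, and adjusted p = 0.448 with an estimated correlation), and Lgals3, the galectin of lipid-associated macrophages, stood at 27.5 ± 8.19 against 135 ± 39.3 FPKM. Of 8 measured inflammation genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.25). The chemokine Ccl8 (-3.32, adjusted p = 7.93e-05), the acute-phase gene Saa3 (-2.97, adjusted p = 0.00294), the matrix protease Mmp3 (-2.61, adjusted p = 1.44e-05) and Wfdc21 (30.2 ± 9.48 against 218 ± 15.3 FPKM, with 44.4 in tAT 2) were among the largest falls. Of 16 extracellular matrix genes 14 fell and 0 rose (14 and 1 adjusted over the list alone; mean -1.01, camera adjusted p = 0.000102, and adjusted p = 0.448 with an estimated correlation), and the collagen gene Col1a1 stood at 45.8 ± 14.8 against 130.3 ± 41.6 FPKM. Of 11 preadipocyte genes 1 rose and 8 fell (1 and 8 adjusted over the list alone; mean -0.43, camera adjusted p = 0.101, or 0.0454 without tAT 1), with Pi16, of fibroblast-like progenitors, at 34.0 ± 13.4 against 87.0 ± 9.09 FPKM. Of 5 measured Schwann cell genes 0 rose and 3 fell (0 and 3 adjusted over the list alone; mean -0.74, camera adjusted p = 0.101), among them Prx, which encodes periaxin of myelinating Schwann cells (-0.60, adjusted p = 0.000239).

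Of 24 tested muscle genes 11 rose (18 adjusted over the list alone; mean 3.97, camera adjusted p = 1.6e-08, and adjusted p = 0.448 with an estimated correlation). This count was 21 without tAT 3, 4 without tAT 1, 2 or 4, 7 without iWAT 1 or 3 and 5 without iWAT 2. Myl1, a fast muscle myosin light chain, and Stac3, of muscle calcium release, were higher by 3.46 and 3.77, values that fell to 0.60 (adjusted p = 0.158) and 0.50 (adjusted p = 0.187) without the muscle-rich libraries. Of 12 endothelial genes 3 rose (3 adjusted over the list alone; mean 0.45, camera adjusted p = 0.00285, and adjusted p = 0.448 with an estimated correlation). Their mean was 0.29 without iWAT 3, with 2 higher, and 5 were higher without iWAT 1. Without the muscle-rich libraries, which left 1 thigh library, the mean was 0.47 and 0 single genes passed. Lists for lymph node, mesothelium, blood and stress response had camera adjusted p = 0.177, 0.453, 0.177 and 0.895, with 1, 0, 2 and 0 members lower, none higher, and 1, 0, 4 and 0 lower adjusted over the list alone. Without iWAT 4 the lymph node list passed (camera adjusted p = 0.0435, with 3 lower), and without iWAT 3 its mean moved from -1.30 to -0.46. There were 4 blood genes lower without tAT 1 or eWAT 2, and 2 stress response genes without tAT 3. Of 8 skin genes 2 were tested, too few for a set test, and 0 passed; 0 of 8 epididymis genes reached the level for testing.

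Of 5 measured posterior Hox genes 1 rose (1 adjusted over the list alone; mean 0.19, or 0.12 without iWAT 2; camera adjusted p = 0.101), Hoxc10 (chromosome 15, 102966796 to 102971893; 0.54). Of 17 anterior Hox genes 4 rose and 3 fell (5 and 3 adjusted over the list alone), with a mean of -0.000328, a median of -0.17 and an upward test (camera adjusted p = 0.261). The sign of this mean turned with single libraries, from -0.0503 without tAT 3 to 0.0453 without tAT 2, and 5 fell without tAT 3 or eWAT 4. Of 11 measured limb and position genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; mean 0.06, camera adjusted p = 0.25). This mean was 0.0330 without tAT 1, 0.0370 without tAT 2 and 0.0949 without tAT 3. Shox2, a limb patterning gene, was higher by 0.75 (adjusted p = 0.000976).

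In all, 1575 genes were higher and 4400 lower in thigh than in inguinal fat, 903 of them by at least 1 on the log2 scale, and the 4 libraries of each depot did not overlap for 33.7% of genes, against 2.86% by chance. The median difference of all genes was -0.11 and -0.0017 after median-of-ratios scaling, which gave 2436 higher and 3002 lower. Without the muscle-rich libraries, which left 1 thigh library, 2738 genes passed. Among the calls lost in this fit, besides Myl1 and Stac3, were Dio2 (1.63, adjusted p = 0.267), Adrb3 (1.24, adjusted p = 0.0638), Prdm16 (0.25, adjusted p = 0.517), Slc2a4 (0.54, adjusted p = 0.088) and Hoxc10 (0.39, adjusted p = 0.0869).

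Thigh fat was next set against brown fat, the depot that expresses the most of the heat-producing genes. In thigh fat 10 of 12 thermogenic genes that muscle hardly expresses and all 13 citric acid cycle genes fell, and 9 of 10 white-selective genes rose. These list calls held (adjusted p = 0.0256, adjusted p = 0.0459 and adjusted p = 0.0267 with an estimated correlation). Ucp1 differed by -4.28 (SE 0.32, adjusted p = 4.16e-08), Cidea by -3.53 (adjusted p = 5.05e-07) and Cox8b by -2.60 (adjusted p = 3.67e-06). Lep was higher in thigh fat (523 ± 149 against 45.9 ± 5.17 FPKM, adjusted p = 2.64e-09), as were Slc7a10 (4.86, adjusted p = 5.08e-11; 8.79 FPKM in BAT 3 and 2.73 to 3.22 in the other BAT libraries) and Adipoq (1.68, adjusted p = 2.49e-10). The median difference of all genes was 0.44 in this comparison and 0.02 after median-of-ratios scaling, so most list means are given under both.

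Of the 12 thermogenic genes that muscle hardly expresses, 10 fell (10 adjusted over the list alone), with a mean of -2.50, or -3.02 after rescaling (camera adjusted p = 6.61e-12, and adjusted p = 0.0256 with an estimated correlation). Dio2 differed by -3.61 and Elovl3 by -3.74, while Adrb3 stood at 133 ± 26.8 against 117 ± 32.2 FPKM (adjusted p = 0.496). Prdm16 stood at 5.12 ± 0.790 against 5.19 ± 1.10 FPKM (adjusted p = 0.971), and was lower in thigh fat after median-of-ratios scaling (-0.47, adjusted p = 0.0176). Zic1 (chromosome 9, 91358058 to 91365810), a transcription factor of classical brown fat, was listed at 0 in the 4 thigh libraries and stood at 2.16 ± 0.357 FPKM in BAT. Of 7 brown-selective genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a mean of -0.45, or -0.83 after rescaling (camera adjusted p = 0.00147, and adjusted p = 0.0306 with an estimated correlation). Of 6 beige-selective genes 5 rose (5 adjusted over the list alone; mean 1.51, or 1.18 after rescaling; camera adjusted p = 0.103).

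All 37 measured complex I subunits fell (37 adjusted over the list alone), with a mean of -1.42, or -1.96 after rescaling, and so did all 22 of complexes II to IV (22 adjusted over the list alone; mean -1.69, or -2.23 after rescaling). Their camera adjusted p-values were 1.23e-38 and 7.04e-27, and both had adjusted p = 0.0612 with an estimated correlation. All 13 citric acid cycle genes fell (13 adjusted over the list alone; mean -1.78, or -2.31 after rescaling; camera adjusted p = 9.11e-20, and adjusted p = 0.0459 with an estimated correlation), Suclg1, of succinyl-CoA synthetase, by 2.33. Of 16 fatty acid oxidation genes 15 fell and 1 rose (15 and 1 adjusted over the list alone; mean -1.62, or -2.16 after rescaling; camera adjusted p = 1.97e-17, and adjusted p = 0.0679 with an estimated correlation), among them Hadhb, of the mitochondrial trifunctional enzyme (-2.62). Of 13 lipogenesis genes 5 rose and 7 fell (5 and 7 adjusted over the list alone; mean -0.35, or -0.89 after rescaling with 2 higher and 7 lower; camera adjusted p = 0.00357, and adjusted p = 0.26 with an estimated correlation). The elongase gene Elovl6 differed by -2.96 and Srebf1, a regulator of lipid synthesis genes, by 1.22, or 0.68 after rescaling. Of 13 glycolysis genes 2 rose and 9 fell (2 and 9 adjusted over the list alone; mean -0.999, or -1.52 after rescaling with 1 higher and 10 lower; camera adjusted p = 1.82e-08, and adjusted p = 0.0351 with an estimated correlation). The enolase gene Eno1 differed by -2.27 and the glucose transporter gene Slc2a1 by 0.71, a call lost after quantile normalization (0.12, adjusted p = 0.423) and without the muscle-rich libraries (0.45, adjusted p = 0.0508). The other rise, of Aldoa, lost its call without any single library except tAT 3 and iWAT 2. Kng2 (1.40 against 117 ± 9.31 FPKM), which encodes a kininogen, the receptor gene Lgr6 (0.409 against 27.5 ± 5.06), Slc27a2, which activates very long fatty acids (5.28 against 92.4 ± 5.82), and the acyl-CoA thioesterase gene Acot11 (4.49 against 88.7 ± 21.5, with 56.5 in BAT 3) were among the largest falls.

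White-selective genes rose, 9 of 10 (9 adjusted over the list alone; mean 2.93, or 2.58 after rescaling; camera adjusted p = 0.000384, and adjusted p = 0.0267 with an estimated correlation), with the adipokine resistin, Retn, at 822 ± 239 against 22.8 ± 6.32 FPKM. Nnat, which encodes the small membrane protein neuronatin, stood at 2037 ± 298 against 38.0 ± 8.44 FPKM (5.72, adjusted p = 4.74e-13), and Sfrp5 was higher by 5.40. Of 18 macrophage genes 17 rose (17 adjusted over the list alone; mean 1.84, or 1.54 after rescaling), and of 16 matrix genes 14 (14 adjusted over the list alone; mean 1.95, or 1.505 after rescaling). Their camera adjusted p-values were 0.00397 and 0.000597, and neither held: adjusted p = 0.515 and adjusted p = 0.438 with an estimated correlation. Col3a1, a fibrillar collagen, stood at 378 ± 104 against 52.0 ± 8.70 FPKM. Of 24 muscle genes 13 rose (0 adjusted over the list alone), with a mean of 3.21 and a test in the other direction (camera adjusted p = 0.777), and muscle transcripts were abundant in 3 libraries of tAT and 2 of BAT. Without tAT 1, 2 or 4 or BAT 1 or 2 1 muscle gene rose. The 12 endothelial genes had a mean of 0.28, with a test in the downward direction, a mean of 0.17 without BAT 4 and a mean of -0.23 after rescaling.

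All 5 measured posterior Hox genes, which mark the hind part of the body, rose against BAT (5 adjusted over the list alone; camera adjusted p = 0.00156, and adjusted p = 0.0918 with an estimated correlation). Hoxc10 stood at 16.6 ± 1.31 FPKM in tAT and was listed at 0 in all 4 BAT libraries, and Hoxa10 stood at 11.7 ± 1.64 against 0.0736. Of 17 anterior Hox genes 7 rose and 2 fell (7 and 2 adjusted over the list alone). Their mean was 0.37 and the test went downward (camera adjusted p = 0.405). After rescaling 5 rose and 6 fell with a mean of -0.0123. The pair that fell was Hoxa4 and Hoxa5 (-2.06 and -1.59). The 7 named mitochondrially encoded genes mt-Atp8, mt-Cytb, mt-Atp6, mt-Co2, mt-Co3, mt-Nd4l and mt-Nd4 were listed at 0 in all 4 BAT libraries, so no fold is given, whereas mt-Nd1 stood at 30849 to 39317 FPKM in BAT and 4146 to 5820 in iWAT.

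Against brown fat, 8783 genes were higher and 1683 lower in thigh fat, 3046 of them by at least 1 on the log2 scale, and libraries did not overlap for 61.2% of genes, against 2.86% by chance. Median-of-ratios scaling, which centres the ratio of the typical gene, gave 4172 higher and 3939 lower. Without the muscle-rich libraries 5924 genes passed.

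Thigh fat was also set against epididymal fat, the visceral white depot. All 12 thermogenic genes shared with muscle rose in thigh fat and all 7 measured mesothelium genes fell, and of the list calls these were the pair that held (adjusted p = 0.0101 and adjusted p = 0.0105 with an estimated correlation). Ucp1 was higher by 7.74 (SE 0.32, adjusted p = 4.72e-10), Cidea by 5.38 (adjusted p = 3.21e-08), Cpt1b by 4.80 (adjusted p = 3.47e-11) and Prdm16 by 1.32 (adjusted p = 5.16e-06). Lep (-1.65, adjusted p = 1.27e-05), Slc7a10 (-1.03) and Adipoq (-0.82) were lower. Of 6 measured beige-selective genes 1 rose and 2 fell (mean -0.41, camera adjusted p = 0.937). Of 7 brown-selective genes 4 rose and 2 fell (mean 0.08, camera adjusted p = 0.0474), a call lost without tAT 3 (camera adjusted p = 0.085) and without several other single libraries. Of 10 white-selective genes 2 rose and 8 fell (mean -1.21, camera adjusted p = 0.0313, or 0.0534 without tAT 3).

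Of the 12 thermogenic genes that muscle hardly expresses 9 rose (9 adjusted over the list alone; mean 2.24, camera adjusted p = 1.44e-06, and adjusted p = 0.104 with an estimated correlation), and of those shared with muscle 12 of 12 (12 adjusted over the list alone; mean 3.05, camera adjusted p = 2.6e-09, and adjusted p = 0.0101 with an estimated correlation). All 13 citric acid cycle genes rose (13 adjusted over the list alone; mean 0.93, camera adjusted p = 3.67e-08, and adjusted p = 0.306 with an estimated correlation). Of the genes of branched-chain amino acid breakdown 9 of 15 rose (10 adjusted over the list alone; mean 0.44, camera adjusted p = 9.31e-05, and adjusted p = 0.393 with an estimated correlation), Slc25a44, the mitochondrial carrier of these amino acids, among them (0.74). Of 24 muscle genes 20 rose and 1 fell (21 and 1 adjusted over the list alone; mean 5.46, camera adjusted p = 9.51e-07, and adjusted p = 0.53 with an estimated correlation). Of the 8 genes named by size of rise 7 were fast muscle genes, such as Ckm, muscle creatine kinase (8.54, adjusted p = 0.0037), and Tnnt3, a fast troponin (8.94, adjusted p = 0.0031). Without the muscle-rich libraries these were 2.996 (adjusted p = 0.0939) and 3.56 (adjusted p = 0.055).

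All 18 macrophage genes fell (18 adjusted over the list alone; mean -2.49, camera adjusted p = 1.5e-07, and adjusted p = 0.393 with an estimated correlation). Trem2, a lipid receptor of macrophages, and Mmp12, the macrophage elastase, differed by -4.09 and -4.10. Of 8 measured inflammation genes 1 rose and 5 fell, of 8 stress response genes 6 fell, of 5 blood genes 5, and of 9 lymph node genes 3. The counts adjusted over the list alone were the same. Their means were -1.83, -0.99, -1.09 and -1.37. Their camera adjusted p-values were 0.0963, 0.135, 0.0963 and 0.31. The lymph node list passed without iWAT 3 (camera adjusted p = 0.016), with 6 lower. All 7 measured genes of mesothelium, the cell layer that covers visceral fat, fell (7 adjusted over the list alone; camera adjusted p = 6.5e-08, and adjusted p = 0.0105 with an estimated correlation). Upk3b stood at 17.5 ± 1.99 FPKM in eWAT and 0.00595 in tAT, where Msln, the mesothelin gene, was listed at 0 in all 4 libraries against 17.4 ± 3.41 in eWAT. The protease inhibitor gene Slpi (chromosome 2, 164354070 to 164389095) stood at 0.483 against 116 ± 16.6 FPKM (-6.29, adjusted p = 1.68e-10) and Agt, the angiotensinogen gene, at 2.37 against 109 ± 24.3 (-5.02, adjusted p = 4.89e-09). Of 16 matrix genes 11 fell (11 adjusted over the list alone; mean -1.14, camera adjusted p = 0.00282, and adjusted p = 0.53 with an estimated correlation). Of 5 posterior Hox genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.000139, and adjusted p = 0.104 with an estimated correlation), and the limb gene Shox2 stood at 16.4 ± 1.12 against 0.127 FPKM.

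Here 3242 genes were higher and 5403 lower in thigh fat, 2082 by at least 1 on the log2 scale, and libraries did not overlap for 45.3% of genes, against 2.86% by chance. The median difference of all genes was -0.08 and 0.02 after median-of-ratios scaling, which gave 4168 higher and 4501 lower. Without the muscle-rich libraries 4842 genes passed.

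**Figure D3:**
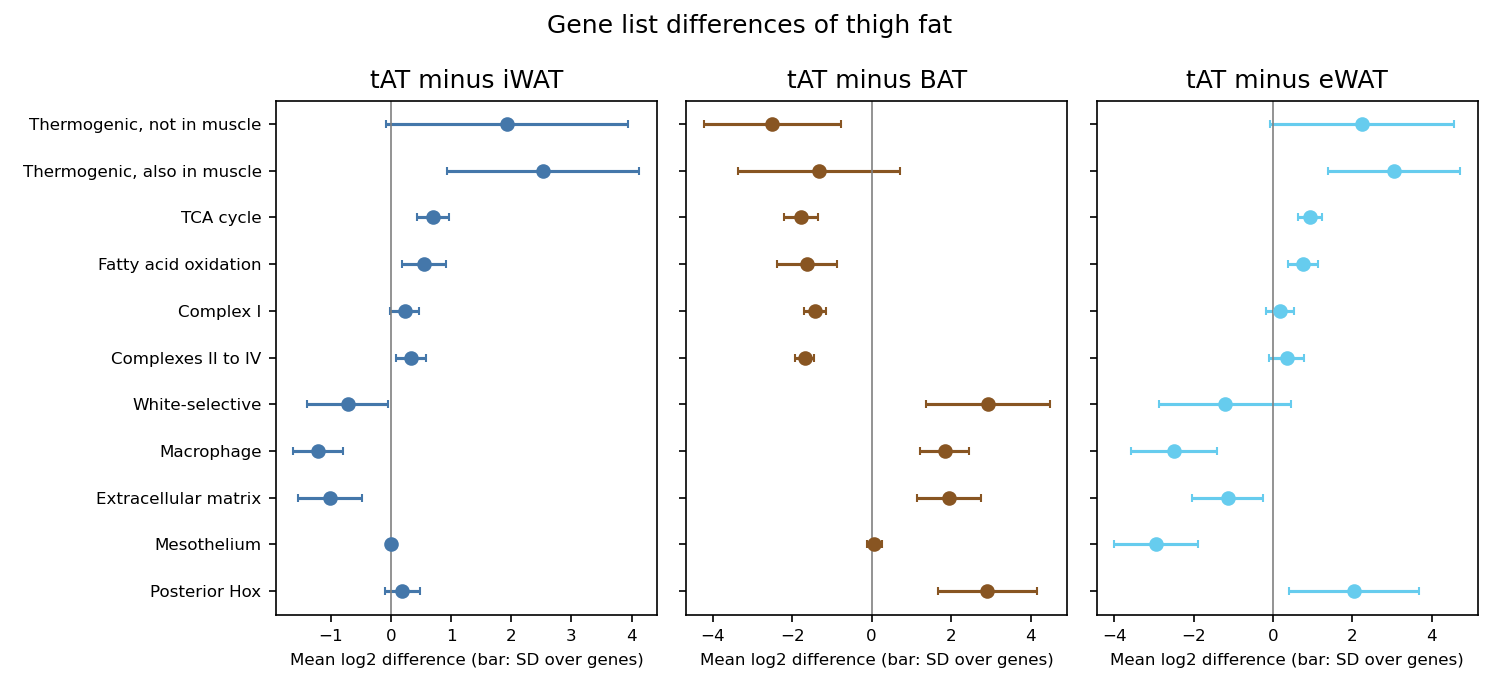
Mean log2 difference of 11 gene lists (points) in thigh fat minus inguinal, brown or epididymal fat; bars are the SD over the genes of a list. Thermogenic genes that muscle hardly expresses lay at 1.93, -2.50 and 2.24, and macrophage genes at -1.21, 1.84 and -2.49.

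The reference depots were compared with each other to give the scale of the brown and white difference. In BAT against iWAT all 12 thermogenic genes that muscle hardly expresses rose (12 adjusted over the list alone; mean 4.43, camera adjusted p = 1.26e-14, and adjusted p = 0.0113 with an estimated correlation), and 9 of 10 white-selective genes fell (9 adjusted over the list alone; camera adjusted p = 0.000951, and adjusted p = 0.0423 with an estimated correlation). Ucp1 differed by 11.82 from iWAT and by 12.02 from eWAT, and Fabp3 by 9.80 and 9.74. In BAT against iWAT 1911 genes were higher and 9225 lower (4695 and 4911 after median-of-ratios scaling), and against eWAT 2275 and 8844 (5182 and 5231). The median difference of all genes was -0.54 and -0.52, and 0.0025 and 0.0063 after that scaling. The white depots differed in genes of mesothelium: in eWAT against iWAT 7 of 7 mesothelium genes rose (7 adjusted over the list alone; mean 2.95, camera adjusted p = 7.77e-23, and adjusted p = 0.000123 with an estimated correlation), with Slpi higher by 6.02 and the chemokine gene Cxcl14 lower (3.27 ± 0.845 against 43.9 ± 6.31 FPKM). There 1271 genes were higher and 828 lower, a total of 2099 that was 1049 without eWAT 1, 1142 without iWAT 1, 1318 without iWAT 4 and 1345 without eWAT 4. It was 3130 without eWAT 3 and 4390 with array quality weights.

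The part of the brown and white difference that thigh fat shared was counted from these calls. Of the 1911 genes higher in BAT than in iWAT, 800 were also higher in tAT than in iWAT, or 41.9% (exact 95% interval 39.6 to 44.1, with genes taken as independent), and 56 were lower. Of these 800 genes 448 were also lower in tAT than in BAT. Of the 9225 genes lower in BAT, 4126 were lower in tAT too, or 44.7% (43.7 to 45.7), and 165 were higher. Of these 4126 genes 3160 were also higher in tAT than in BAT on the deposited scale. The counts in both directions depend on that scale. Median-of-ratios scaling gave 4695 genes higher and 4911 lower in BAT than in iWAT. For tAT against iWAT it gave 2436 higher and 3002 lower, and for tAT against BAT 4172 higher and 3939 lower. The shared part of the higher genes was then 37.6%. The shared part of the lower genes, and the counts of 448 and 3160, were not recounted after that scaling. On the deposited scale independent lists would share 201 and 2708 genes. Both comparisons used the same iWAT libraries, and with these split 2 and 2 the share was 25.6 to 32.2% for higher and 32.3 to 37.1% for lower genes. The split lists shared 447 to 530 higher and 2749 to 3220 lower genes, where independent lists would share 78.5 to 127 and 1644 to 2028.5. With fewer iWAT libraries per fit, 674 to 1157 genes were higher in tAT, against 1575, so lost calls may have lowered the share as well. Across genes, the differences correlated with r = 0.608, against 0.491 in 20 simulations of unchanged groups, and their covariance was 0.437 against 0.0341, a difference of 0.403. The simulated r was set by construction, since the shared and the separate errors were drawn equally large, so the r values do not measure a shared part. The simulations also gave tAT and BAT the spread of the iWAT libraries.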

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

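The tests of explanations here, for thermogenic, muscle and mitochondrial genes, and the fits without the muscle-rich libraries were chosen only after the results were seen. The fits with the muscle score as a covariate and with median-of-ratios scaling, on which some of these tests draw, had been chosen in advance.

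Thermogenic genes were higher in thigh than in inguinal fat by a mean of 1.93 on the log2 scale, and muscle tissue or the scaling of libraries might have made this difference. Neither adjustment removed the difference: the mean was 2.23 with the muscle score as a covariate and 1.99 after median-of-ratios scaling. Rescaling could remove little, since the median difference of all genes was -0.11, which is small beside 1.93. The covariate was a weak check too, since the list was chosen for genes that muscle hardly expresses. Brown fat or its RNA mixed into the thigh samples stays open: 20 brown-fat genes implied a median brown share of 6.41%, with 70% of them within 2-fold of it. A uniform admixture would hold all of them near that median, but Kng2 implied 0.688% and Chchd10 23.0%. The high end of the spread cannot decide this, since the 20 genes include Cox7a1, Cox8b, Cpt1b and Fabp3, which muscle also expresses. They also include Fabp3-ps1, whose reads may be shared with Fabp3. Muscle transcripts can raise an implied share but leave the low end unexplained. There Kng2 implied at most 1.38% and Lgr6 at most 2.46% in any thigh library, against 2.51 to 10.2% for Ucp1. Both genes were low in tAT, at means of 1.40 and 0.409 FPKM, so they alone do not settle it. A difference between the depots themselves, such as beige cells in the thigh, is the hypothesis the design names and stays open as untested.

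Skeletal muscle genes were abundant in tAT 1, 2 and 4 and in BAT 3 and 4 and low in the other libraries of these depots. For the brown libraries, a muscle-like programme of all brown fat is argued against, since the muscle scores of BAT 1 and 2, 0.917 and 0.763, lay below the iWAT range of 1.496 to 3.29, and a programme of thigh fat would not reach them. Muscle tissue taken with the fat stays open in both depots: 23 of the 27 measured muscle genes in each of tAT 1, 2 and 4, and 24 in each of BAT 3 and 4, lay above all iWAT and eWAT values and those of the muscle-poor libraries of the same depot, and the exceptions were the slow-fibre genes Tnnc1, Tnnt1 and Tnni1 and, in the thigh, Myh7. For a muscle-like programme of all thigh fat, the muscle score of tAT 3 was 2.13, inside the iWAT range, but a single library cannot exclude it. For the thigh libraries, muscle tissue and such a programme cannot be told apart here, since tAT 3 is the only thigh library low in these transcripts.

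Of 13 mitochondrially encoded protein genes, 8 were listed at 0 in all 4 BAT libraries, and failed estimates in the deposited values or a loss of mitochondrial transcripts could lie behind this. Loss is argued against, since the other 5 genes all lay above every library of the other depots in all 4 BAT libraries. Failed estimates had the values they need: the lowest ratio of BAT to iWAT among these 5 genes was 3.68 and the highest 8.85.

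In all 6 comparisons only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes. A share of 1 in 35 is the smallest this test can give, and every other split mixed the depots. Chance is therefore not excluded, also because the libraries of a depot may be technical repeats. The real count and the highest of the other splits were 5975 and 933 for tAT against iWAT, 10466 and 544 against BAT, 8645 and 4420 against eWAT, 11136 and 0 for BAT against iWAT, 11119 and 2 for BAT against eWAT, and 2099 and 524 for eWAT against iWAT.

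Single libraries stood far from the other 3 of their depot in 8 of 121 list scores and in 18 of 178 sets of values of named genes, where chance gives about 5%. In tAT 3 the muscle score was 2.13, against 6.80 to 7.54. The same library was lowest for Stac3 (1.57 FPKM), Myl1 (166), Tnnt3 (26.9), Myh4 (7.50), Ckm (15.2), Atp2a1 (8.57), Tnni2 (16.7), Mylpf (28.3) and Tnnc2 (20.9), all muscle genes. Its adipokine score was 6.51, against 6.41 to 6.42. Wfdc21 stood at 44.4 FPKM in tAT 2, against 25.2 to 25.7. In eWAT 3 the epididymis score was 1.197, against 0.0613 to 0.128, and its epididymis genes summed to 368 FPKM. The same library stood apart in the beige-selective score (3.05, against 2.73 to 2.76), Ckm (2.78 FPKM, against 0.542 to 0.788) and Tnnc2 (9.60 FPKM, against 2.11 to 2.62). In eWAT 1 the creatine and calcium cycling score was 3.58, against 3.25 to 3.30, and in eWAT 4 Myl1 stood at 45.5 FPKM, against 57.1 to 58.2. In iWAT 3 the lymphocyte and lymph node score was 4.11, against 0.742 to 1.12. In iWAT 4 the lipogenesis score was 5.84, against 6.67 to 6.83. In iWAT 2 Dio2 stood at 6.73 FPKM, against 0.203 to 0.323, and Agt at 5.27, against 16.2 to 16.4. In BAT 1 Cox7a1 stood at 3352 FPKM, against 2737 to 2807, and the skin score was 0.305, against 0.239 to 0.243. In BAT 3 Acot11 stood at 56.5 FPKM, against 98.1 to 101, and Slc7a10 at 8.79, against 2.73 to 3.22.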

How the results depend on the processing

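The settings were chosen in advance, except the fits with zeros set to missing, without the muscle-rich libraries and without eWAT 3, which were chosen after seeing the data. Of 300 named differences 279 passed, and 231 of these kept their direction and call in every setting chosen in advance that tested them. The filter of 5 FPKM left 42 of the 300 untested, and 209 of the 231 had a value under it. Leaving out 1 library ended the call of 24 and reversed 0: against iWAT Bckdhb, Cd40, Hoxb7, Hspb7, Myh4, Neb, Nos2, Pfkp and Prdm16, against BAT Aldoa, Cd2, Egr2, Fos, Krt19, Mbp, Myh4 and Tnnt3, and against eWAT Ccl19, Epsti1, Ndufa2, Ndufa7, Nrip1, Tbx1 and Vwf. Leaving out 1 library at a time gave 4825 (without tAT 4) to 6499 (without tAT 3) genes for tAT against iWAT, 9678 to 10618 against BAT, 7747 to 9262 against eWAT, 10717 to 11408 for BAT against iWAT, 10759 to 11474 for BAT against eWAT, and 1049 (without eWAT 1) to 3130 (without eWAT 3) for eWAT against iWAT. The mean of the thermogenic list ranged over 1.81 to 2.06, -2.62 to -2.37 and 2.12 to 2.36 against iWAT, BAT and eWAT, and the share of brown-high genes also higher in thigh over 36.2 to 43.2%. A minimum log2 difference of 1 left 903, 3046, 2082, 4674, 5182 and 330 genes in the comparisons in that order, by its construction. The muscle score as a covariate left 3974 genes for tAT against iWAT and 5460 against eWAT, and ended 35 named calls. Without the muscle-rich libraries, with fewer samples, 2738, 5924 and 4842 genes passed against iWAT, BAT and eWAT, 65 named calls ended and 12 differences reversed: Tbx1 (-1.20, -0.0301 and -0.54 against iWAT, BAT and eWAT), Myh4 (-0.0940), Neb (-0.25) and Tbx15 (-0.0125) against iWAT, Aldoa (-0.49) and Mbp (-0.0176) against BAT, and Aldoa (-0.0140), Nrip1 (-0.0429), Ndufa2 (0.10) and Ndufa7 (0.0484) against eWAT. Reversed means a turned sign only, and several of these values, such as those of Tbx15 and of Aldoa against eWAT, were too small to be read as opposite differences. After median-of-ratios scaling Mbp (-0.24) reversed against BAT, and after quantile normalization Mbp (-0.27) and Krt10 (-0.40). These settings moved the median difference of all genes against BAT from 0.44 to 0.02 and -0.04. A smaller rise, such as that of Mbp (0.25 without tAT 4), turns its sign by such a shift. For Krt10 the cause was not tested. Quantile normalization gave 2440 higher and 3275 lower genes against iWAT, 3498 and 4210 against BAT, and 4241 and 4376 against eWAT, and 4958 and 4646 for BAT against iWAT and 5571 and 4904 against eWAT. Array quality weights gave 4390 genes for eWAT against iWAT. With an estimated correlation the thermogenic list against eWAT kept its mean of 2.24 but not its call (adjusted p = 0.104); the cause of these changes was not tested. The share of brown-high genes was 32.4% with no filter, 37.6% after median-of-ratios scaling, 36.5% after quantile normalization, 34.7% with 2 depots alone, 39.5% with the covariate and 33.3% without the muscle-rich libraries; it was not run with array weights. Zeros set to missing changed 0 of 287 named differences. Sequencing depth is unknown, so its limit on low genes could not be stated.

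The replicate block ended 7 named calls, added 1 and gave 6007, 10411, 8646, 11160, 11135 and 2066 genes in the 6 comparisons. No pairing by number was seen: over 24 pairs with a shared number the correlation of deviations ranged from -0.274 to 0.230. Its median was 0.0246, and 1 library correlated best with its own number. This cannot exclude a pairing, since the libraries also differed in muscle transcripts. The muscle-poor tAT 3 gave -0.274 with the muscle-rich BAT 3 and 0.325 with the muscle-poor BAT 1.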

Other observations

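The tests of genes highest or lowest in thigh fat and of selenoprotein genes were chosen only after the values were seen, as were the genes named here.

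Some genes set the thigh apart from white and brown fat alike. Genes were counted if they passed in every tAT comparison on the deposited scale. Of these, 232 had all 4 thigh libraries, tAT 3 included, above all 12 libraries of the other depots, and 86 had them below. Of the 232 genes 13 were listed at 0 in all 4 BAT libraries, 7 of them mitochondrially encoded, which leaves 219 others. Some entries, such as Gm37282 and RP24-155C13.8 (28.9 FPKM in tAT), had identical means in every depot, so these counts hold some signals more than once. Neat1, a long noncoding RNA of nuclear paraspeckles, averaged 782 FPKM in tAT against 404 in iWAT, 357 in BAT and 305 in eWAT. Dbp, a transcription factor of the circadian clock output, averaged 89.2 FPKM against 49.5, 42.9 and 35.0. Celsr2, an adhesion receptor of planar cell polarity, and Hoxa6, of body position, were also highest in the thigh, as were Atp1b2, a subunit of the sodium pump, and Speg, a kinase of striated muscle. Of these, Atp1b2, Speg and Hoxa6 were lower in tAT 3, the library poor in muscle transcripts, at 5.51, 7.61 and 1.23 FPKM against means of 19.0, 15.6 and 2.01 over the 4 thigh libraries. The highest mean of another depot was 4.51, 4.99 and 0.628 FPKM. Genes lowest in the thigh included Id2, an inhibitor of differentiation factors, Ctsz, a lysosomal protease, Prdx5, a peroxidase, and Ckb, brain-type creatine kinase.

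Genes of selenoproteins, which carry selenocysteine in their chain, ranked high by their mean over the 16 libraries. Of 24 annotated genes 20 were tested, and 17 of these lay in the top 5% of 12422 tested protein-coding genes by mean FPKM, with a median percentile of 99.6. None of 10000 random lists of 20 had a median as high, and the highest was 84.7. The set was picked after the values were seen, so this comparison describes the ranking and is no independent test. Txnrd3, a thioredoxin reductase, averaged 1384 FPKM and Sepn1, a calcium-handling selenoprotein, 1768 FPKM, whereas relatives without selenocysteine ranked lower, for example Gpx7 at a percentile of 67.4, Gpx8 at 80.1 and Sephs1 at 44.2. No explanation of this ranking was tested.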
